A study of Mus musculus with 6 samples.

How the data were processed

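Total RNA from gingiva of 12-week-old C57BL/6 mice was measured in 6 libraries, 3 labelled Plg WT and 3 labelled Plg KO. Per the labels' protocols, libraries were made with Illumina's Nextera XT kit, which does not mark the strand of the RNA, and sequenced as 37 bp paired-end reads on a NextSeq500. Without strand, reads from a gene and from an overlapping or antisense gene cannot be told apart. Per the submitters' processing notes, STAR 2.5.2a, edgeR, limma and DESeq2 were used, with the mouse builds GRCm38.p3 and mm10, and the notes as used here give no role or order for them. The counting tool, its treatment of reads shared between genes and the gene annotation are not given in the sources used here.

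A pair of tables was used. The first holds raw counts per gene as deposited, for 48709 genes, and 22 further entries for spike-in and transgene sequences that name no gene and took at most 3.55e-05% of a library. These were left out of library sizes and tests. The second holds CPM values deposited by the authors after TMM scaling, for 21948 genes and 1 entry that names no gene. The genes in it are those with a count above 5 in at least 1 library, with 0 exceptions when tested against the count table. Multiplying each CPM column by 1 constant gave whole reads for 100% of its values, within a tolerance of 0.01 of the value or 0.01 read. High counts meet this tolerance in any case. Rounded, the reads equalled the raw counts of the same genes, and they were tested as an added alternative. Gene names came from the deposited CPM table for 21658 identifiers and from GENCODE release M21 for 26691 more, which left 360 without a name. Positions came from the same release, on GRCm38, and were found for 17717 of the tested genes.

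Total gene counts per library were 36006829, 28184139 and 31776002 in Plg WT 1, 2 and 3 and 36429150, 26183389 and 35651489 in Plg KO 1, 2 and 3. At these depths 3 counts, the most that a count of 0 allows, equal 0.0824 to 0.115 CPM per library. Reads carry no molecular identifiers, so such limits cover counting error only. Any pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 21.4 to 111.4 over genes with at least 20 counts in the pair, so no pair was taken as copies of 1 library.

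The main test was edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood F test on the raw counts, TMM normalization, genes kept by filterByExpr (17757 genes) and Benjamini-Hochberg adjustment over them. The design held the genotype only. A gene is called at an adjusted p under 0.05. CPM values in the text are TMM-normalized counts scaled to a common library size in this fit, except for Plg, and are given as mean ± SD. The SE beside a log2 change is the change divided by the square root of its F value. The common biological coefficient of variation was 0.225 and the median log2 change of all genes -0.00.

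Gene lists for neutrophils, other cell types of the tissue and of its neighbours, inflammation, matrix, epithelium and general cell functions were fixed before the data were examined. Of their symbols, 2 were not matched. All 42 lists had at least 5 tested genes and were tested with camera from limma 3.58.1 (preset inter-gene correlation 0.01), with camera's estimated correlation and with fry. Genes to be named were also fixed before the data were examined. They were Plg, then, among called genes with a mean of at least 1 CPM and groups that do not overlap, the 12 with the largest rise and the 12 with the largest fall, of which only 8 existed, and, for each of the 16 lists described in full, the 4 members with the smallest p. Unnamed gene models and immunoglobulin variable segments were left out, and some genes that these rules select are not reported here. Ddx3y and Xist were fixed beforehand as markers of sex. Col17a1 and the genes that only the closing observations name were chosen after their values were seen.

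Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a stricter filter (at least 1 CPM in at least 3 libraries), limma-voom, limma-trend on log2 of the deposited CPM plus 0.5, the replicate number as a block, leaving out each library, thinning all libraries to the smallest total, removing the 10 most abundant genes, a test of changes above 1.5-fold, an adjusted p under 0.10 and removing genes on the sex chromosomes. A term for the sex read from Xist and Ddx3y and the reads recovered from CPM were added after seeing the data. The scripts were tested on simulated data for Plg KO against Plg WT, 3 libraries against 3, with 17354 genes passing the filter. The edgeR test recovered 30 of 97 genes changed 2-fold and 76 of 96 changed 4-fold, with 12 of 17161 unchanged genes called. DESeq2 recovered 52 and 86, with 51 unchanged genes called, and limma-voom 29 and 73, with 11. In a simulation over 17757 genes with 1 list raised 2-fold, camera called that list (adjusted p = 1.14e-44) and 1 of 38 lists that share no gene with it. Genes were drawn independently there, so it cannot show how often camera calls lists of correlated genes by chance. In the real data the estimated correlation reached 0.92, in the oxidative phosphorylation list.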

Results

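The series measured gene expression in the gingiva, the mucosa that surrounds the teeth, of 12-week-old C57BL/6 mice. It compared mice that lack Plg (Plg KO) with wild-type littermates (Plg WT). Plg encodes plasminogen, the precursor of plasmin, which is the main protease that dissolves fibrin clots. The question the series names is how fibrin bears on neutrophil function at mucosal barriers. Each group had 3 RNA sequencing libraries, and total gene counts ran from 26183389 in Plg KO 2 to 36429150 in Plg KO 1. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical for the 2 libraries of like sex in each group. Sex-linked transcripts, given below, show that each group held at least 2 animals.

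Plg itself (ENSMUSG00000059481, GRCm38 chromosome 17, 12378608 to 12419385) was close to undetected in this tissue. It had 2 counts over the 3 Plg WT libraries, all in Plg WT 3, and 2 counts over the 3 Plg KO libraries, all in Plg KO 1. Plasminogen is made mainly in the liver, and at this depth the gene gives no check of the genotype labels. For counting error alone, 2 counts allow up to 6.30 (one-sided 95% Poisson limit), which is 0.0656 CPM (counts scaled to a common library size) over the Plg WT libraries and 0.0641 CPM over the Plg KO libraries. Sex-linked transcripts differed between libraries and were balanced between groups. The Y-linked gene Ddx3y had 1475 counts in Plg WT 3 and 1838 in Plg KO 1 and at most 2 in any other library, whereas Xist had 10 and 2 counts in those libraries and 917 to 1129 in the other 4.

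Among the 42 genes called of 17757 tested, some inflammatory, neutrophil-attracting and matrix-degrading transcripts were higher in gingiva without Plg. Several transcripts of the circadian clock were lower. The largest rises among the called genes were in Ptgs2, the inducible cyclooxygenase that makes prostaglandins (17.6-fold), Clec4e, a myeloid receptor for microbial glycolipids (15.8-fold), and Mmp10, a stromelysin that degrades matrix (8.41-fold). Osm, a cytokine of the interleukin-6 family, rose 8.08-fold, and Il1b, which encodes interleukin-1 beta, rose 7.22-fold. The largest falls were in Dbp, a clock-controlled transcription factor (7.52-fold lower), and Cidec, a protein of fat-cell lipid droplets (5.39-fold lower). Of 17757 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 34 were higher and 8 lower in Plg KO at an adjusted p under 0.05. In all 42 of them the 3 libraries of one group lay above the 3 of the other, which held for 14.7% of all tested genes and is 10% by chance. At an unadjusted p under 0.05 there were 1642 genes, against 888 expected by chance. DESeq2 called 274 higher and 128 lower, so its share of higher calls was 68.2% against 81.0% in the edgeR fit. In simulated data DESeq2 called 51 unchanged genes and edgeR 12, so more of DESeq2's calls may be false. The edgeR counts depended on single libraries, at 184 higher and 35 lower without Plg WT 1, 1 and 1 without Plg WT 2, 1 and 2 without Plg WT 3, 2 and 1 without Plg KO 2, and 2 and 1 without Plg KO 3. Leaving out 1 library can hardly turn genes whose groups do not overlap, so it adds little that all 42 kept their direction in these fits.

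**Figure D1:**
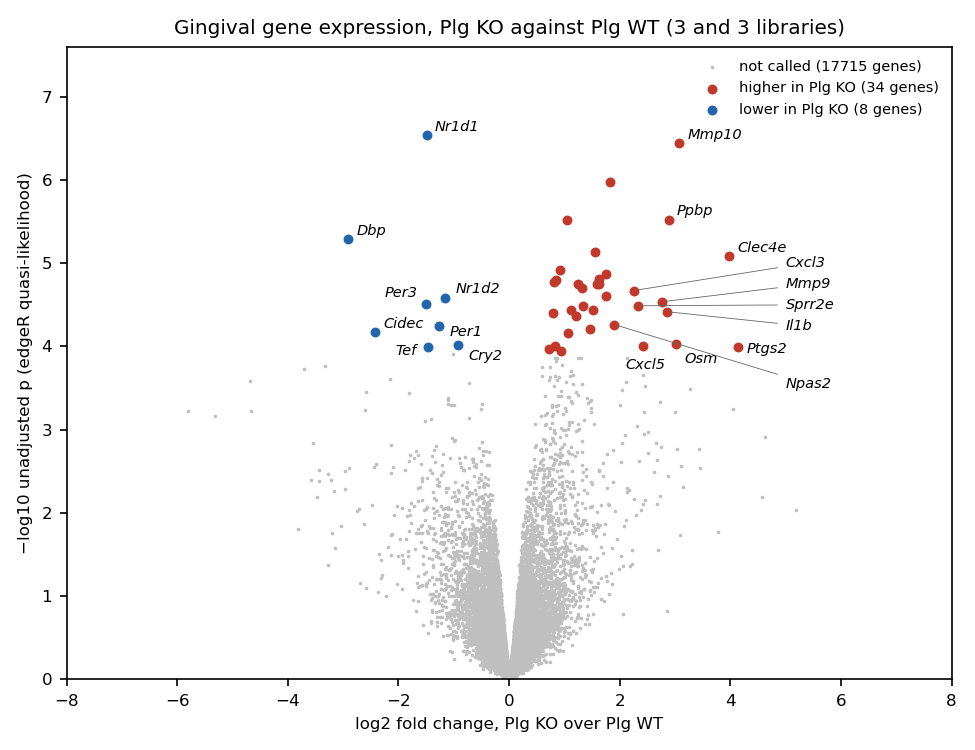
Each point is 1 of 17757 tested genes, with the log2 fold change of Plg KO over Plg WT on the x axis and the negative log10 of the unadjusted edgeR p on the y axis. Red points are the 34 genes called higher and blue points the 8 called lower at an adjusted p under 0.05, and the labelled genes run from Dbp at -2.91 to Ptgs2 at 4.13.

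Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227) went from 0.139 ± 0.0949 CPM in Plg WT to 2.60 ± 1.14 CPM in Plg KO (SD, n = 3 each), a log2 change of 4.13 ± 0.55 (SE) with an adjusted p of 0.0446 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its Plg WT level rests on 14 counts over 3 libraries, against 242 in Plg KO. Clec4e, with 16 counts in Plg WT and 257 in Plg KO, went from 0.165 ± 0.0586 to 2.69 ± 0.605 CPM. Mmp10 (ENSMUSG00000047562, chromosome 9, 7502352 to 7510240) went from 3.60 ± 0.601 to 30.3 ± 4.62 CPM, with a log2 change of 3.07 ± 0.18 and an adjusted p of 0.0032. Osm rose from 0.281 ± 0.0359 to 2.31 ± 0.919 CPM and Il1b from 1.72 ± 0.615 to 12.4 ± 3.45 CPM.

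**Figure D2:**
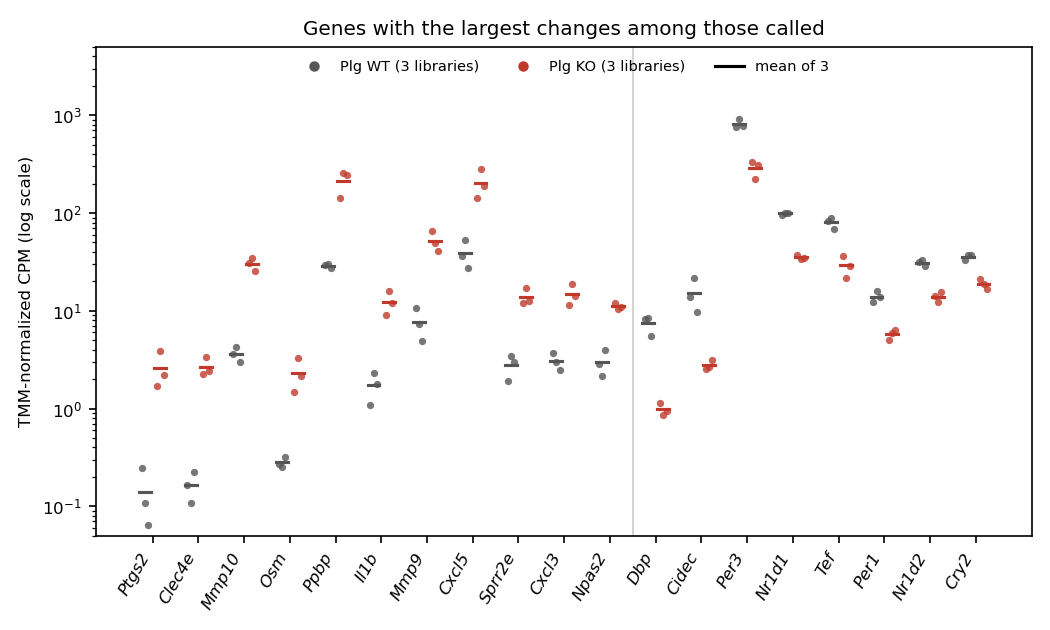
TMM-normalized CPM (log axis) of the 11 genes with the largest rises, on the left, and the 8 with the largest falls, on the right, among the genes called. Each point is 1 library, grey for Plg WT and red for Plg KO, and each bar is the mean of 3 libraries. The groups do not overlap in any of these genes, and Mmp10 has means of 3.60 CPM in Plg WT and 30.3 CPM in Plg KO.

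Of the 8 genes that fell, 7 belong to or are driven by the circadian clock. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), a repressor that acts on Arntl, fell 2.81-fold from 99.1 ± 3.15 to 35.3 ± 2.07 CPM (SD, n = 3 each), with the smallest p of all genes (adjusted p = 0.0032 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its relative Nr1d2 fell 2.22-fold. The period genes Per3 and Per1, which repress the clock's own activators, fell 2.83-fold and 2.41-fold, and the cryptochrome Cry2 fell 1.90-fold. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) went from 7.43 ± 1.67 to 0.980 ± 0.142 CPM, and the related factor Tef fell 2.75-fold. Npas2, a clock activator that pairs with Arntl, moved the other way, rising 3.74-fold from 2.98 ± 0.905 to 11.2 ± 0.804 CPM. The hour at which tissue was taken is not given in the sources used here. A difference in hour between the groups, if there was one, could not be told apart from genotype for any gene. None of the clock genes named here was in a list fixed before the data were examined.

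Genes were also grouped in 42 lists of pathway members and cell type markers fixed before the data were examined. The camera test, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 42 lists, called 15 lists higher and 8 lower in Plg KO. With an estimated correlation it called 1 list higher, the matrix metalloproteinases, and 0 lower (10 and 2 at an unadjusted p under 0.05). The estimate was 0.001 for that list and -0.0081 for the coagulation list, both below the preset value. Correlation between members is thus not why p rose for these 2 lists. How much of the rise in the other lists came from correlation was not tested. The rotation test fry, which asks whether the genes of a list move on balance one way, called 8 higher and 0 lower (11 and 3 at an unadjusted p under 0.05). These 8 were the cell cycle, neutrophil marker, neutrophil chemokine, matrix metalloproteinase, proinflammatory cytokine, osteoclast, basal epithelium and coagulation lists. Some genes stand in several lists, such as Mmp9 in 3 of them.

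**Figure D3:**
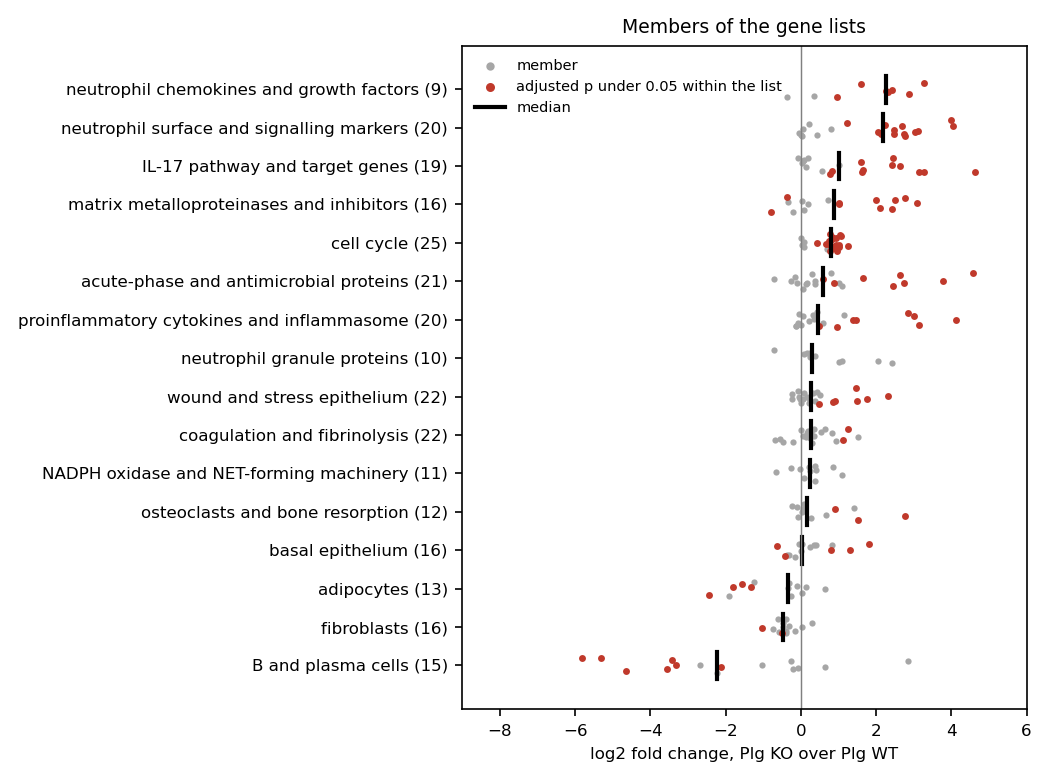
Log2 fold change of Plg KO over Plg WT (x axis) for the tested members of 16 lists, with the number of members in brackets. Each point is 1 gene, red where its p adjusted over the list alone is under 0.05, and each black bar is the list's median, which runs from -2.23 for B and plasma cells to 2.26 for neutrophil chemokines.

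Lists of transcripts that attract or mark neutrophils were called higher in Plg KO, and both missed with an estimated correlation (adjusted p = 0.0505 for each). Among chemokines, Ppbp, whose product is processed to a ligand of the neutrophil receptor Cxcr2, rose 7.38-fold from 28.9 ± 1.63 to 213.3 ± 62.8 CPM, Cxcl5 rose 5.32-fold and Cxcl3 rose 4.78-fold. Csf3, the growth factor that drives neutrophil production, had a log2 difference of 3.27 ± 0.52 (adjusted p = 0.0772 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 9 tested members of the chemokine and growth factor list, 3 were higher over all genes and 7 adjusted over the list alone. The list had a median log2 change of 2.26 and was called (adjusted p = 8.03e-27 in camera, adjusted p = 0.0505 with an estimated correlation). Of 20 neutrophil surface and signalling markers, 2 were higher over all genes, Clec4e and the gelatinase Mmp9 (6.80-fold), and 13 adjusted over the list alone. Hdc, the histamine-forming enzyme of granulocytes, and the inhibitory receptor Cd300lf had log2 differences of 2.12 ± 0.29 and 2.46 ± 0.38 (adjusted p = 0.0504 and 0.0718). This list had a median of 2.17 and was called (adjusted p = 2.60e-30 in camera, adjusted p = 0.0505 with an estimated correlation). Close homologs among the Cxcl genes can share reads, so the split between them is uncertain.

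Genes for the stored granule proteins and the oxidative burst of neutrophils did not pass the test as groups. The granule list, with the collagenase Mmp8, the iron-binding proteins Lcn2 and Ltf, and Ngp, had 0 of 10 members called by edgeR over all genes or adjusted over the list alone (1 by DESeq2 and 0 by limma-voom), a median of 0.31 and an adjusted p of 0.0593 in camera. The log2 differences were 2.43 ± 0.67 for Mmp8, 1.09 ± 0.63 for Ltf and 2.06 ± 1.33 for Ngp, and Lcn2 had 2.74 ± 0.793 CPM in Plg WT and 5.50 ± 3.08 in Plg KO. Ltf had 256.2 CPM in Plg WT 1, 41.2 and 62.0 CPM in Plg WT 2 and 3 and 188.0 to 295.9 CPM in Plg KO. The list passed when Plg WT 1 (adjusted p = 0.0043) or Plg KO 1 (adjusted p = 0.00998) was left out. The list of NADPH oxidase subunits and genes for neutrophil extracellular traps had 0 of 11 members called either way (0 by DESeq2 and by limma-voom) and an adjusted p of 0.130, or 0.00476 without Plg WT 1. Its members with the smallest p were Padi4 and Padi2, which citrullinate proteins, with log2 differences of 0.84 ± 0.33 and 1.10 ± 0.48, the GTPase Rac2 at -0.68 ± 0.31 and the integrin Itgb2 at 0.38 ± 0.22. Padi2 had 18.2 CPM in Plg WT 1, 6.82 and 4.68 CPM in Plg WT 2 and 3 and 15.3 to 24.9 CPM in Plg KO. Plg WT 2 and 3, in which Ltf and Padi2 were lowest, were also the 2 lowest libraries in the mean level of the salivary gland list (-0.97 and -0.89, against 0.68 in Plg WT 1 and 0.09 to 0.69 in Plg KO, on a centred log2 scale). At an unadjusted p under 0.05, edgeR's test counted Mmp8 and Padi4 among the members of these lists.

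The proinflammatory cytokine list was called higher, but not with an estimated correlation (median 0.46, adjusted p = 4.44e-14 in camera, adjusted p = 0.152 with an estimated correlation). Ptgs2, Osm and Il1b were the 3 of 20 members called over all genes, and 8 were higher adjusted over the list alone. Il1rn, the natural antagonist of the interleukin-1 receptor, had a log2 difference of 0.95 ± 0.14 (adjusted p = 0.0582 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 19 genes of the IL-17 pathway and its targets, Cxcl5 was called over all genes and 11 were higher adjusted over the list alone. The calprotectin subunit S100a9 had 25.8 ± 9.28 CPM in Plg WT and 139.7 ± 86.4 in Plg KO. The cytokine Il24 had 4 counts over the Plg WT libraries and 104 over the Plg KO libraries. The median of this list was 1.0 (adjusted p = 8.17e-17 in camera, adjusted p = 0.152 with an estimated correlation). Of 21 acute-phase and antimicrobial genes, edgeR called 0 over all genes (8 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom) and 8 were higher adjusted over the list alone, with a median of 0.58 (adjusted p = 4.64e-08 in camera, adjusted p = 0.152 with an estimated correlation). Its members with the smallest p were the peptidoglycan-binding Pglyrp4 at a log2 difference of 0.87 ± 0.12, S100a9 at 2.44 ± 0.47, S100a8 at 2.63 ± 0.61 and Wfdc21 at 2.73 ± 0.72.

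Matrix-degrading enzymes formed the list whose call held with an estimated correlation. Of 16 matrix metalloproteinases and inhibitors, Mmp10 and Mmp9 were higher over all genes. Adjusted over the list alone, 8 were higher and 2 lower. Mmp9 went from 7.62 ± 2.86 to 51.9 ± 12.9 CPM. The aggrecanase Adamts4 had 1.31 ± 0.631 CPM in Plg WT and 5.22 ± 0.826 in Plg KO, and the membrane-bound protease Adam8 had 23.5 ± 3.43 and 47.5 ± 9.97 (adjusted p = 0.0892 and 0.0928 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list had a median of 0.87 (adjusted p = 8.64e-15 in camera, adjusted p = 0.0432 with an estimated correlation).

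The list of coagulation and fibrinolysis, the system Plg belongs to, was called higher, but not with an estimated correlation (median 0.26, adjusted p = 3.09e-04 in camera, adjusted p = 0.142 with an estimated correlation). Of 22 tested members, edgeR called 0 over all genes (7 higher and 1 lower at an unadjusted p under 0.05, 2 higher by DESeq2 and 0 by limma-voom) and 2 were higher adjusted over the list alone, Plat, the tissue plasminogen activator, and Procr, the protein C receptor. Plat had 24.6 ± 1.48 CPM in Plg WT and 53.2 ± 11.9 in Plg KO, and Procr 14.5 ± 4.08 and 34.5 ± 7.61. The log2 difference was -0.49 ± 0.16 for F13a1, the fibrin cross-linking factor XIII subunit, and 0.64 ± 0.22 for the urokinase Plau.

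The osteoclast and bone resorption list was called, but not with an estimated correlation (median 0.17, adjusted p = 2.18e-05 in camera, adjusted p = 0.152 with an estimated correlation), and the members that moved are not specific to resorption. Mmp9 and Tnfrsf11b were the 2 of 12 members called over all genes, and 3 were higher adjusted over the list alone. Tnfrsf11b encodes osteoprotegerin, a decoy receptor known to restrain osteoclast formation, and rose 2.87-fold from 7.27 ± 1.13 to 20.9 ± 3.48 CPM. The integrin Itgb3, which platelets also carry, and the fusion receptor Dcstamp had log2 differences of 0.89 ± 0.27 and 1.41 ± 0.83.

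The basal epithelium list was called, but not with an estimated correlation (median 0.02, adjusted p = 2.62e-04 in camera, adjusted p = 0.152 with an estimated correlation) or on limma-voom values (adjusted p = 0.0560 in camera). The log2 changes of its members had both signs, 9 positive and 7 negative. Of 16 basal epithelium genes 3 were called over all genes, among them Lama3, which rose 2.48-fold, and Lamb3, which rose 1.74-fold. Adjusted over the list alone, 3 were higher and 2 lower, the latter Dst and Col17a1, which anchor keratinocytes at hemidesmosomes. Dst had a log2 difference of -0.63 ± 0.15. Of 22 wound and stress epithelium genes, Sprr2e and Sprr2f, small proline-rich proteins of the cornified envelope, were called, rising 5.01-fold and 3.36-fold, and 7 were higher adjusted over the list alone. Sprr2d and Sprr2h had log2 differences of 0.85 ± 0.12 and 1.46 ± 0.24. The list's median was 0.26 (adjusted p = 6.21e-11 in camera, adjusted p = 0.239 with an estimated correlation). The Sprr2 genes are close paralogs, and how shared reads were divided between them is not given in the sources used here.

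The cell cycle list was called higher, but not with an estimated correlation (median 0.79, adjusted p = 5.66e-39 in camera, adjusted p = 0.152 with an estimated correlation). Of 25 tested members, 24 had a positive log2 change, 2 were called over all genes and 20 were higher adjusted over the list alone. Birc5, which serves chromosome segregation in dividing cells, rose 2.07-fold from 34.0 ± 0.795 to 70.2 ± 3.82 CPM, and Ccna2, the cyclin of S phase and mitotic entry, rose 2.38-fold. The mitotic kinase Plk1 and the anaphase activator Cdc20 had log2 differences of 0.83 ± 0.12 and 0.74 ± 0.11 (adjusted p = 0.0504 and 0.0587 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

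Markers of B cells, fat cells and fibroblasts were called lower as lists, but not with an estimated correlation (adjusted p = 0.152, 0.239 and 0.152), and 1 single gene was called over all genes. Of 15 B and plasma cell genes, edgeR called 0 over all genes (7 lower and 1 higher at an unadjusted p under 0.05, 7 lower by DESeq2 and 0 by limma-voom) and 7 were lower adjusted over the list alone, with a median of -2.23 (adjusted p = 2.04e-14 in camera, adjusted p = 0.152 with an estimated correlation). The B cell receptor component Cd79a had 779 counts in Plg WT, of which 565 were in Plg WT 1, and 30 in Plg KO, and Ms4a1, which encodes the antigen CD20, had 308 and 5. Iglc1, a light chain constant gene that can share reads with its copies, had 303 and 7 counts. The mean member level, on the log2 scale and centred over the 6 libraries, was 2.05 in Plg WT 1, 1.05 in Plg WT 2, 0.69 in Plg WT 3, -2.11 in Plg KO 1, -2.11 in Plg KO 2 and 0.44 in Plg KO 3. Of 13 adipocyte genes, Cidec was called, falling from 15.0 ± 6.11 to 2.78 ± 0.311 CPM, and 4 were lower adjusted over the list alone. The adipokines Cfd, Retn and Adipoq had log2 differences of -1.81 ± 0.29, -1.57 ± 0.38 and -1.32 ± 0.36. The list's median was -0.35 (adjusted p = 1.17e-07 in camera, adjusted p = 0.239 with an estimated correlation). Of 16 fibroblast genes, edgeR called 0 over all genes (7 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom) and 2 were lower adjusted over the list alone, with a median of -0.48 (adjusted p = 2.08e-07 in camera, adjusted p = 0.152 with an estimated correlation). The fibroblast members with the smallest p were the microfibril protein Mfap4 at a log2 difference of -1.04 ± 0.20, the actin-severing Gsn at -0.51 ± 0.12, the growth factor receptor Pdgfra at -0.73 ± 0.22 and the chemokine Cxcl12 at -0.58 ± 0.19.

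Other lists were called with 0 members passing edgeR's test or limma-voom over all genes, and with 0 to 1 members passing DESeq2 and 0 to 7 at an unadjusted p under 0.05. Upward, these were glycolysis and hypoxia (median 0.21, adjusted p = 4.72e-04 in camera, adjusted p = 0.493 with an estimated correlation), the unfolded protein response (median 0.18, adjusted p = 0.00576, adjusted p = 0.533 with an estimated correlation), salivary gland (median 0.66, adjusted p = 0.00795, adjusted p = 0.533 with an estimated correlation) and junctional and odontogenic epithelium (median 0.49, adjusted p = 0.0171, adjusted p = 0.413 with an estimated correlation). Downward, they were fibrillar collagens and matrix (median -0.44, adjusted p = 1.70e-07, adjusted p = 0.413 with an estimated correlation), Schwann cells and nerve (median -0.62, adjusted p = 2.34e-05, adjusted p = 0.479 with an estimated correlation), the type I interferon response (median -0.76, adjusted p = 3.07e-05, adjusted p = 0.533 with an estimated correlation), mast cells (median -0.76, adjusted p = 0.00506, adjusted p = 0.239 with an estimated correlation) and keratinised epithelial differentiation (median -0.20, adjusted p = 0.00576, adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 4 mast cell genes were lower, 2 junctional epithelium genes and 1 glycolysis gene were higher, and 0 genes of the other lists in this group passed. For all of these lists but mast cells, another split of the libraries into 3 and 3 gave a smaller unadjusted p in camera. Such splits mix the genotypes. For the type I interferon response that p was 2.74e-16 in camera, against 1.10e-05 in the real split. For collagens it was 4.40e-15 against 4.45e-08, and for Schwann cells 1.11e-23 against 7.81e-06. The interferon call ended without Plg WT 3 (adjusted p = 0.398). The salivary gland, junctional epithelium and keratinised differentiation calls ended without Plg WT 2 (adjusted p = 0.0535, 0.0535 and 0.0501), without Plg WT 3 (0.111, 0.175 and 0.268) and without Plg KO 3 (0.0650, 0.0729 and 0.228), and the unfolded protein call ended without Plg WT 2 (0.0501), Plg WT 3 (0.0972) and Plg KO 1 (0.156).

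The remaining lists did not pass in camera, which looks for a shift of the members one way. Camera's adjusted p was 0.0693 for T and NK cells (median -0.25), 0.0810 for the interferon-gamma response and MHC class II (-0.14), 0.0959 for osteoblasts and mineralised matrix (-0.39), 0.129 for cytosolic ribosomal proteins (-0.08), 0.216 for complement (-0.02), 0.417 for oxidative phosphorylation (0.05), 0.444 for dendritic and Langerhans cells (0.11), 0.444 for tight junctions and desmosomes (0.04), 0.533 for blood and lymphatic endothelium (-0.11), 0.660 for tongue papillae and taste cells (-0.04) and 0.704 for erythroid cells and platelets (-0.56). It was 0.722 for skeletal muscle (0.00), 0.887 for hair follicle and sebaceous gland (-0.11), 0.887 for immediate early genes (-0.04), 0.887 for mitochondrially encoded transcripts (0.03), 0.952 for monocytes and macrophages (0.10) and 0.957 for pericytes and smooth muscle (-0.00). The direction of camera and the sign of the median differed for skeletal muscle, immediate early genes, monocytes and macrophages, and pericytes. Over all genes, 1 member of these lists was called, Ppbp among the platelet genes. Adjusted over the list alone, 2 monocyte and macrophage genes were higher and 2 lower. For complement 1 was higher and 2 lower, and 1 dendritic cell gene and Ppbp were higher. Fry's mixed test, which counts changes either way, gave these lists adjusted p = 0.00265, 0.0113, 0.00763 and 0.00361, in this order. The other remaining lists did not pass it. Leaving out 1 library brought some of the remaining lists past camera's threshold. These were T and NK cells without Plg WT 3 (adjusted p = 1.29e-04) or Plg KO 2 (0.00395), interferon-gamma without Plg WT 1 (0.00117) or Plg KO 1 (7.97e-05), osteoblasts without Plg WT 3 (0.00141) or Plg KO 3 (0.00167), and ribosomal proteins without Plg WT 1 (0.0281) or Plg KO 1 (0.0168). Likewise, skeletal muscle passed without Plg KO 1 (1.65e-07) or Plg KO 3 (0.00426), in opposite directions, platelets without Plg WT 1 (0.0116), immediate early genes without Plg WT 2 (0.0142) and oxidative phosphorylation without Plg KO 1 (4.23e-04).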

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

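The term for sex and the reads recovered from CPM were chosen after seeing the data, and all other alternatives before the data were examined. The 42 genes called by edgeR's quasi-likelihood test kept their direction in all 21 alternative settings. Their groups did not overlap in the main fit, so a change of direction was hardly possible and this says little about robustness. Counts stayed within 1.5 times of 34 higher and 8 lower with RLE or upper-quartile factors, the stricter filter, limma-voom and thinning to the smallest library. They did so as well with removal of the 10 most abundant genes, removal of sex-chromosome genes and the recovered reads. The recovered reads equal the raw counts, so that fit differs from the main one only in the genes kept and says little. The calls numbered 274 and 128 with DESeq2 and 122 and 40 without a filter on low counts. They numbered 95 and 26 at an adjusted p under 0.10, and 4 and 2 in the test of changes above 1.5-fold. With the sex term 54 were higher, and limma-trend on the deposited CPM gave 13 lower. Leaving out 1 library gave 1 to 184 higher and 1 to 35 lower. The extremes were the fit without Plg WT 1, with 219 calls, and the fits without Plg WT 2, Plg WT 3, Plg KO 2 or Plg KO 3, in which 2, 3, 3 and 3 of the 42 genes remained called, whereas 29 of them remained without Plg KO 1. These fits have 1 library fewer, and beyond that the cause was not tested. In the 16 lists described in full and among the largest changes, 67 genes were named. In the settings that gave them a value, 0 of them reversed. They were picked for a large change or a small p, so this too says little about robustness. The deposited CPM table gave no value for Plg, and the list of tongue papillae and taste cells had too few genes under the stricter filter to be tested.

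With the replicate block, edgeR called 2 genes higher and 0 lower, with 1105 genes at an unadjusted p under 0.05. Libraries of the same number did not deviate together, with correlations across genes of -0.26, -0.01 and -0.22 for numbers 1, 2 and 3. Of the 6 libraries 0 correlated best with its own number. Deviations were taken from means of 3 libraries, and the libraries of numbers 1 and 3 differ in sex. The correlations therefore cannot exclude a shared litter, cage or day. The labels do not say that a number marks one, so the numbers are not read as pairs. Under the block, the list of erythroid cells and platelets passed (adjusted p = 0.0423), hair follicle and sebaceous gland turned direction (0.982), and 0 genes near Plg were called.

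For the gene lists, the estimated correlation left 1 list higher and 0 lower, and fry 8 higher and 0 lower. With an estimated correlation, camera's adjusted p was 0.0505 for neutrophil surface markers and for neutrophil chemokines, 0.142 for coagulation, 0.152 for the IL-17 pathway, proinflammatory cytokines, acute-phase proteins, B and plasma cells, fibroblasts, osteoclasts, basal epithelium and the cell cycle, and 0.239 for wound epithelium, adipocytes and mast cells. It was 0.413 for fibrillar collagens and junctional epithelium, 0.479 for Schwann cells, 0.493 for glycolysis, 0.533 for the type I interferon response, salivary gland and the unfolded protein response, and 0.637 for keratinised differentiation. With fry the adjusted p was 0.0887 for the IL-17 pathway, 0.0900 for fibroblasts, 0.120 for acute-phase proteins, 0.138 for B and plasma cells and mast cells, 0.144 for wound epithelium, 0.153 for adipocytes, 0.310 for junctional epithelium and glycolysis, 0.315 for collagens, 0.326 for the unfolded protein response, 0.360 for Schwann cells, and 0.507 for the type I interferon response, keratinised differentiation and salivary gland. Without a filter the adjusted p was 0.0485 for neutrophil granule proteins, 0.0482 for the interferon-gamma response, 0.0498 for osteoblasts and 0.0506 for junctional epithelium, and platelets (0.816) and hair follicle (0.928) turned direction. With the stricter filter granule proteins passed (0.0124), and dendritic cells (0.900), platelets (0.998) and hair follicle (0.672) turned direction. On limma-voom values basal epithelium missed (0.0560), ribosomal proteins passed (0.0276), and monocytes and macrophages (0.892) and pericytes (0.991) turned direction. With the sex term T and NK cells passed (0.0281), and monocytes and macrophages (0.931) and platelets (0.820) turned direction. The cause of these changes was not tested. None of the lists that turned direction in these settings was called in the main test.

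Leaving out 1 library gave 12 to 17 lists higher and 7 to 11 lower. Adjusted p ran from 0.0043 to 0.116 for granule proteins, from 0.00476 to 0.8004 for NADPH oxidase and trap genes, from 0.241 to 0.970 for monocytes and macrophages, from 1.29e-04 to 0.976 for T and NK cells, from 1.36e-21 to 0.398 for the type I interferon response, from 7.97e-05 to 0.627 for the interferon-gamma response, from 0.00141 to 0.895 for osteoblasts, from 1.76e-06 to 0.268 for keratinised differentiation, from 9.12e-06 to 0.175 for junctional epithelium and from 0.0622 to 0.686 for tight junctions. It ran from 1.69e-13 to 0.111 for salivary gland, from 1.65e-07 to 0.495 for skeletal muscle, from 0.228 to 0.895 for endothelium, from 0.145 to 0.932 for pericytes, from 0.0116 to 0.977 for platelets, from 0.575 to 0.977 for hair follicle, from 0.482 to 0.854 for tongue papillae, from 4.23e-04 to 0.977 for oxidative phosphorylation, from 3.05e-05 to 0.156 for the unfolded protein response, from 0.0142 to 0.981 for immediate early genes, from 0.0607 to 0.977 for mitochondrial transcripts and from 0.0168 to 0.963 for ribosomal proteins. The genes called within 10 Mb of Plg numbered 0 to 5, with 0 in the fits without Plg WT 2, Plg WT 3, Plg KO 2 or Plg KO 3. Depth limits mainly Plg itself and genes near 3 counts per library, and thinning all libraries to the smallest total gave 34 genes higher and 10 lower.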

Other observations

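The bounds of the tests below were chosen after the results were seen, except for the splits of the libraries. The window around Plg and its Fisher exact test were fixed before the data were examined. The genes of the first 2 paragraphs and the list of clock genes were chosen after their values were seen.

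Of the 42 called genes, 24 belong to none of the gene lists, 9 of them clock genes. Among the others, Aldh1a3, which makes retinoic acid, rose 2.92-fold from 34.1 ± 6.41 to 99.6 ± 2.84 CPM (SD, n = 3 each), and the serine proteases Prss22 and Tmprss11g rose 3.10-fold and 2.31-fold. Vnn1, a pantetheinase, rose 2.51-fold, the zinc importer Slc39a4 rose 2.18-fold, and the aldo-keto reductase Akr1b8 rose 1.90-fold (adjusted p = 0.0184 to 0.0266 for these 6 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

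Further genes of cell division were called beside those in the cell cycle list. Cenpa, the histone variant of centromeres, rose 1.80-fold, the histone chaperone Asf1b rose 2.09-fold, and Pimreg, a mitotic regulator, rose 1.91-fold. Vmp1, a membrane protein needed for autophagy, rose 1.78-fold from 563.2 ± 51.0 to 1000.0 ± 56.4 CPM, and U90926 rose 3.09-fold.

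Other ways of splitting the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 42 genes and the highest other split called 4, so 1 of 10 splits reached the real value. For the gene lists the real split called 23, and so did the highest other split, Plg WT 1, Plg WT 2 and Plg KO 3 against the rest, so 2 of 10 splits reached it, and every split called at least 10 lists. For 15 of the 23 called lists the real split gave the smallest camera p of the 10. The other called lists were glycolysis, the unfolded protein response, salivary gland, junctional epithelium, collagens, Schwann cells, the type I interferon response and keratinised differentiation. The split of Plg WT 1, Plg KO 2 and Plg KO 3 against the rest had 3079 genes at an unadjusted p under 0.05, against 1642 in the real split, and 0 called. This may point to a structure of the libraries apart from genotype, but the split was picked as the most extreme of the 10. Of the 42 lists 7 had their 3 highest and 5 their 3 lowest levels in these libraries. For a split fixed beforehand, 10% of lists would be set apart by chance. The widest gaps on a centred log2 scale were 0.56 for the interferon-gamma response (lowest), 0.51 for skeletal muscle (highest), 0.36 for the type I interferon response (lowest), and 0.32 for neutrophil granule proteins and for salivary gland (highest).

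The clock genes raise a question about the hour of collection. Of 18 clock genes, a list drawn up after the calls were seen, 9 were called. Arntl, which rose 2.77-fold, and the genes that peak with it had a median log2 change of 0.73. Nr1d1, Dbp, Per1 and the others of the opposite phase had -1.27, a difference of 2.0014. Library scaling or depth moves both arms one way. The called genes of both arms were known when the list was drawn up, so the difference restates the calls and is no separate test of scaling. All 9 clock genes that were not called had a log2 change with the sign of their arm, and in 6 of them the groups did not overlap. A difference in the time of day at which the groups were collected may account for this and cannot be told apart from an effect of genotype or inflammation on the clock, since no collection times are given in the sources used here. Such a difference would bear on genes outside the clock as well.

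Called genes clustered near Plg. Within 10 Mb of it on chromosome 17, 3 of 113 tested genes were called against 39 of 17644 elsewhere (odds ratio 12.3, 95% confidence interval 2.40 to 39.7, two-sided Fisher exact p = 0.0024), which argues against chance placement. Among them were Qk (10202601 to 10319854) and Igf2r (12682406 to 12769664), higher in Plg KO by 3.02-fold and 1.75-fold, so loss of reads to strain variants, which lowers counts, is argued against for the called genes. The fits without Plg WT 2, Plg WT 3, Plg KO 2 or Plg KO 3 called 0 genes in the window, as did the replicate block. These fits called only 2 or 3 genes in all, so this says little. Without Plg KO 1 the window held 4 called genes and without Plg WT 1 it held 5 (two-sided Fisher exact p = 9.8e-05 and 0.013). At an unadjusted p under 0.05 it held 18 genes, 13 higher and 5 lower (two-sided Fisher exact p = 0.0211). Read loss stays open for the 5 lower. Within 20 Mb of Plg, 4 of 334 tested genes were called (two-sided Fisher exact p = 0.0078), among them the protease Prss22 (23993534 to 23998100). Flanking sequence of another strain or the targeted allele may act on these neighbours, and the called share was 5.46 percentage points higher within 5 Mb than between 5 and 10 Mb (3 of 55 against 0 of 58, two-sided Fisher exact p = 0.112), too few genes to decide.

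The list of neutrophil surface and signalling markers had a higher mean level in every Plg KO library than in any Plg WT library, which the granule protein list did not (-0.42 in Plg KO 1 against 0.05, -0.48 and -0.27 in Plg WT). More blood left in the Plg KO tissue is argued against, since 4 haemoglobin transcripts had a mean log2 change of -0.65 ± 0.44 (SE over libraries), below the median of 2.17 of the neutrophil markers. A single library carrying the rise is argued against as well, since the lowest Plg KO level of the marker list lay 1.36 above the highest Plg WT level, more than the 0.23 between the Plg WT libraries. A larger number of neutrophils and a higher level of these transcripts per cell are both open as hypotheses and cannot be told apart in whole tissue. Granule protein genes, which are transcribed mainly before neutrophils mature, did not pass the test as a list in the main fit. They passed as a list without Plg WT 1, without Plg KO 1, and with the stricter filter or none.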
